A study of Mus musculus with 8 samples.

How the data were processed

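The samples were virus-specific CD8 T cells of mouse spleen at day 8 of infection, 4 control and 4 Atg7-deleted, each hybridised to 1 array. Per the labels, total RNA was extracted with a Qiagen column kit, amplified with a NuGEN kit and biotin-labelled. The deposited values are intensity values, 1 probe set signal per row on a linear scale. The software that made them, the scaling between arrays and the background correction are not given in the sources used here. The deposited arrays were not equalised: 2% trimmed mean signals ran from 348 to 529.7. Which part of the difference in brightness between the groups came from the cells is not known. Groups were taken from the genotype in the labels, which call the samples biological replicates 1 to 4. No 2 arrays held identical values, and correlations within groups lay between 0.985 and 0.993.

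Of 45101 probe sets, 64 control probe sets were left out, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Only probe sets with 1 symbol were used, which gave 18193 genes. The gene ID of 34741 probe sets was found in the RefSeq gene table of GRCm38.p6, and 0 symbols needed updating. No coordinates are given, since the series names no genome build. Signals were transformed as log2(signal + 16), which understates differences of dim genes. The probe set with the highest mean over all 8 arrays stood for its gene, and the dimmest 25% of genes were left out, leaving 13644.

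Atg7-deleted and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the 33 lists, and again with the correlation estimated per list. Exact permutation tests used all assignments of 4 of the 8 arrays. A list's shift is the mean log2 difference of its tested members minus that of all other tested genes. Design, alternatives, lists and the rule for named genes were fixed before the data were examined. The rule named Atg7, the 12 genes with the largest rise and the 12 with the largest fall among genes that passed without overlap between groups, filled by smallest p where fewer passed, and of each list up to 3 tested members with the smallest p. Genes filled in by p are given as values only. The p-values belong to fitted differences, which take in a 0.22 log2 rise of the median gene. Choosing list members by p therefore favoured members that rose, also in lists that fell. Camera compares the fitted differences of a list, divided by their standard errors, with those of all other genes. Genes with small standard errors gain more from a shared rise, so the camera p does not test the shift itself. Fos, Jun, Il7r, Prickle1, H2-Oa and Cyp4f16 fall outside the rule and were chosen after their values were seen.

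The lists held 833 entries, of which 769 were on the array. They covered anti-apoptotic genes, ATF4 amino acid response, autophagy cargo receptors, autophagy machinery, B cell markers, CD4 T cell and regulatory T cell markers, cell cycle genes, cytotoxic effector genes, dendritic cell markers, endocytosis and membrane traffic, ER stress and unfolded protein response, erythroid and platelet markers, fatty acid oxidation, gamma-delta T cell markers, glycolysis, heat shock response, immediate early genes, inhibitory receptors and exhaustion genes, interferon response, lysosome, macrophage and monocyte markers, memory precursor and naive genes, mitochondrial dynamics and biogenesis, mTORC1 with amino acid and iron uptake, neutrophil markers, NK cell markers, NRF2 oxidative stress response, oxidative phosphorylation, p53 targets, pro-apoptotic genes, proteasome, sterol and fatty acid synthesis and TCA cycle. Of the 735 different list genes on the array, 30 stand in more than 1 list, among them Tfrc, Hspd1, the Sdh genes of the TCA cycle and oxidative phosphorylation lists, and Fas, Bbc3, Pmaip1 and Tnfrsf10b of the p53 and pro-apoptotic lists.

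The steps were tested on simulated data, with the control means and residual variances of the real genes, over 13644 genes. Of 100 genes changed by 1 log2, 79% were recovered, and of 100 changed by 2 log2, 100%, with 11 of 13408 unchanged genes called. The simulated noise was independent between genes, with no brightness difference between groups and no division of the replicates. The simulation therefore checks that the steps run correctly and does not give the power or the rate of false calls on the real arrays. Alternatives were quantile normalization, centring on array medians, no filter on dim genes or a filter of 50%, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, a variance trend with a robust prior, array weights, the replicate number as a block, an offset of 64, each array left out in turn, every probe set tested, an estimated correlation and fry. Chosen after seeing the data were a term for replicates 1 and 2 against 3 and 4, that term with quantile normalization, fits within each of these sets, a fit without control arrays 1 and 2, the exact permutation of each list's mean per array, and an estimated correlation under these later settings. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.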

Results

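Gene expression was measured on 8 one-colour Affymetrix arrays, 1 per sample, in virus-specific CD8 T cells from mouse spleen. The cells carried a T cell receptor that binds the GP33 peptide of lymphocytic choriomeningitis virus (LCMV) on the class I molecule Db, and were taken at day 8 after infection with the Armstrong strain. Of the samples, 4 came from mice with floxed Atg7 alleles and no Cre, called control here, and 4 from mice that also carried Cre under the granzyme B promoter, called Atg7-deleted here. Atg7 encodes an enzyme that lipidates the LC3 proteins during autophagosome formation. The series compares gene expression in these cells with and without ATG7 at the peak of their expansion. Median probe set signals were 27.1, 23.9, 35.9 and 33.6 on control arrays 1 to 4 and 32.9, 38.4, 42.9 and 30.03 on Atg7-deleted arrays 1 to 4, and the number of arrays limits the precision of every comparison. Because the fitted difference of the median gene was 0.22 log2 and -0.0033 after quantile normalization, gene differences below are log2 differences, Atg7-deleted minus control, relative to the median gene. The fitted differences, to which the p-values belong, are 0.22 higher.

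The Atg7 probe set with the highest signal, which stood for the gene, read 227 ± 155 on the Atg7-deleted arrays and 991 ± 149 on the control arrays (mean ± SD of signal, n = 4 each). Its signals were 911, 821, 1106 and 1126 on control arrays 1 to 4 and 171, 458, 159 and 122 on Atg7-deleted arrays 1 to 4, so that all 4 Atg7-deleted values lay below all 4 control values. The relative log2 difference was -2.43 with an SE of 0.34. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 arrays can give, and the limma p adjusted over all genes was 0.112. The other 3 Atg7 probe sets overlapped between the groups. Their relative log2 differences were -0.018 (exact permutation p = 0.371), -0.49 (exact permutation p = 0.286) and -0.022 (exact permutation p = 0.457). Where each probe set lies relative to the floxed part is not given in the sources used here, and a probe set outside that part checks nothing. Without Atg7-deleted replicate 2, whose signal was the highest of its group, the difference was -2.81 and passed the threshold (adjusted p = 0.00250), and it also passed after centring each array on its median (adjusted p = 0.0304). With the mean of its 4 probe sets standing for the gene, the difference was -0.73. Over all alternatives the adjusted p ran from 0.00250 to 0.467. The difference was -1.92 within replicates 1 and 2 and -2.94 within replicates 3 and 4.

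**Figure D1:**
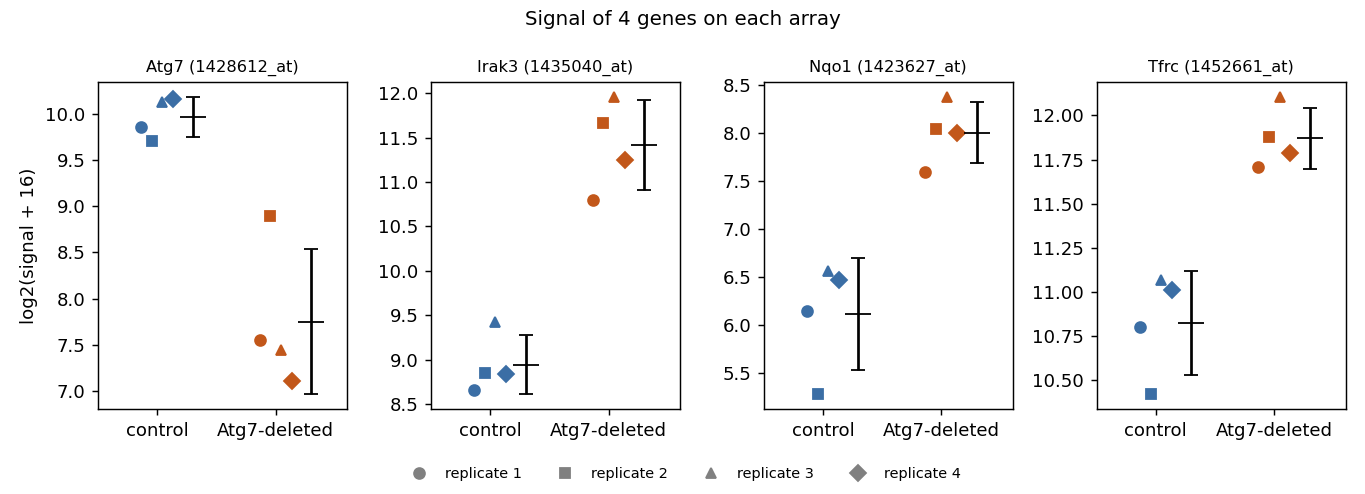
Signals of Atg7, Irak3, Nqo1 and Tfrc on each array, as log2 of signal plus 16, by group; symbols mark the replicate number, and the bar beside each group is the mean with its SD (n = 4). All 4 Atg7-deleted arrays lie below the control arrays for Atg7 and above them for Irak3, Nqo1 and Tfrc.

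Irak3, which encodes an inhibitor of Toll-like and interleukin-1 receptor signalling, was the 1 gene of 13644 tested that passed the threshold. It rose by 2.26 relative log2 in the Atg7-deleted cells (SE 0.26, limma adjusted p = 0.0386), with signals of 2841 ± 955 against 486 ± 125 (mean ± SD, Atg7-deleted against control, n = 4 each). A second Irak3 probe set read 589 against 83.0. No gene passed in the lower direction, where 40 genes had an unadjusted p under 0.05, against 2552 in the higher direction. Together these made 2592 genes where 682 would be expected of independent genes with no difference. Other groupings of the same arrays gave as many: 3 of the 35 splits into 4 and 4 did, the real one included, and the highest of the others gave 3348. That split set the 4 arrays with the lowest median signals apart. The other, with 3284, set the 4 with the lowest trimmed mean signals apart, so this count followed array brightness. After quantile normalization 2 genes passed, Irak3 and Dab2ip, and 1111 genes had an unadjusted p under 0.05, 640 higher and 471 lower. Without control arrays 1 and 2, the arrays with the lowest median signals, 1276 genes did, 974 of them higher. The fitted median difference was then 0.060. Within replicates 1 and 2 it was 0.36, with 5103 such genes, 5029 higher. Within replicates 3 and 4 it was 0.078, with 1038 such genes, 730 higher. The Irak3 call was lost without control replicate 1 (adjusted p = 0.198), 2 (0.104) or 4 (0.229) and without Atg7-deleted replicate 2 (0.105), 3 (0.0790) or 4 (0.199), while its difference stayed between 2.12 and 2.45. The call also ended with no filter on dim genes (adjusted p = 0.0725) and with array weights (adjusted p = 0.0578), and over all alternatives the adjusted p ran from 0.00381 to 0.504. Within replicates 1 and 2 the Irak3 difference was 2.12 and within replicates 3 and 4 it was 2.39.

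The other genes named in the higher direction did not pass the threshold with genotype alone in the fit, and for each of them all 4 Atg7-deleted values lay above all 4 control values. Nqo1, a quinone reductase controlled by the transcription factor NRF2, read 245 ± 56.3 against 57.3 ± 25.1, a difference of 1.67 (SE 0.28, adjusted p = 0.112). Tfrc, the transferrin receptor, read 3746 ± 459.6 against 1826 ± 351, a difference of 0.83 (SE 0.17, adjusted p = 0.112). Abcb6, a mitochondrial porphyrin transporter, stood at 0.93 (SE 0.14, adjusted p = 0.0624), and Dab2ip, a Ras GTPase-activating protein, at 0.94 (SE 0.14, adjusted p = 0.0624). With a term for replicates 1 and 2 against 3 and 4, chosen after seeing the data, Abcb6, Dab2ip and Nqo1 passed (adjusted p = 0.0416 each), and with that term and quantile normalization none did. Dab2ip, Nqo1 and Tfrc passed with centred arrays, Dab2ip after quantile normalization, Abcb6 and Dab2ip with an offset of 64 or with the dimmest 50% of genes left out, and Abcb6 with the mean of its probe sets. Over all alternatives the adjusted p ran from 0.0342 to 0.655 for Abcb6, 0.0304 to 0.655 for Dab2ip, 0.0304 to 0.504 for Nqo1 and 0.0391 to 0.655 for Tfrc. With the mean of its probe sets Dab2ip stood at 0.49 (adjusted p = 0.147), its dimmer probe set being at 0.020. Socs2, a suppressor of cytokine signalling, stood at 0.83, the DNA repair gene Rad54b at 0.69 and the reelin receptor gene Lrp8 at 0.56. Cdc23, a subunit of the anaphase-promoting complex, stood at 1.04 on the probe set standing for it, and at -0.59 and -0.0038 on its others, so its probe sets disagreed in direction. Omd, Tmem205 and Pcdhgc4 stood at 1.08, 0.61 and 0.58, with mean control signals of 22.7, 51.9 and 57.5. All 4 Atg7-deleted values exceeded all 4 control values in 1749 genes and lay below them in 25, together 13.0% of the tested genes, where chance gives 2.86% of independent genes. After quantile normalization, which removes the brightness difference shared by all genes, the numbers were 366 above and 294 below, 4.84% together. Of the 35 splits of the arrays, 2 gave as many genes without overlap, the real one included, and the other of these gave 2067.

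In the lower direction Atg7 had the smallest p, and the 11 genes that followed it were dim, each with a mean control signal under 60. Tgm2, a transglutaminase, stood at -1.25 on the probe set standing for it, with signals of 16.4 ± 5.22 against 51.9 ± 18.3. Its 5 other probe sets lay between -0.59 and 0.19, and the gene stood at 0.063 when probe sets ending in _x_at or _s_at were left out. Prom1 stood at -0.88, T2 at -0.94 and Eno2, the neuronal enolase, at -0.71 with signals of 37.3 ± 7.25 against 58.5 ± 6.70. Gng11 stood at -0.77, Tcea3 at -0.76, Fgf23 at -0.70 and AI593442 at -0.66. The cDNA-named genes 2210010C04Rik, 2410012E07Rik and 2310040G24Rik stood at -1.22, -0.76 and -0.72. Their adjusted p ran from 0.178 to 0.188, and none passed.

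Cell cycle genes were higher as a group: 36 of 39 tested members lay above the median gene in the Atg7-deleted cells. The list rose by 0.33 log2 against all other genes (camera adjusted p = 1.64e-13, and adjusted p = 0.865 with an estimated correlation). The mitotic kinase gene Plk1 stood at 0.46 (826 ± 103 against 513 ± 77.0), the kinetochore gene Cenpf at 0.43 and the mitotic kinesin gene Kif2c at 0.63. No member passed over all genes, and 35 passed adjusted over the list alone, or 4 after quantile normalization, which left a shift of 0.30. The shift was 0.23 within replicates 1 and 2 and 0.42 within replicates 3 and 4, a division of the arrays by which immediate early genes differed.

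Genes of the NRF2 oxidative stress response rose as a list, by 0.19 (camera adjusted p = 0.0153, and adjusted p = 0.865 with an estimated correlation), with 20 of 27 tested members above the median gene. Over all genes 0 members passed, and adjusted over the list alone 4 passed, or 1 after quantile normalization. The 4 included Nqo1 at 1.67 (adjusted p = 0.00159 over the list alone), the small Maf gene Mafg at 0.76 (0.0107) and Gpx4, which reduces lipid peroxides, at 0.36 (0.0448), where leaving out 1 array gave 0.22 to 0.50 for Gpx4. The NRF2 shift was 0.20 within replicates 1 and 2 and 0.18 within 3 and 4, and with the dimmest 50% of genes left out its adjusted p was 0.0638. In the ATF4 amino acid response (shift 0.13, camera adjusted p = 0.320, 14 of 23 tested members above the median gene), 3 members passed adjusted over the list alone and 0 over all genes: the stress protein gene Nupr1 at 1.51, the asparagine synthetase gene Asns at 0.79 and the serine synthesis gene Phgdh at 0.29. After quantile normalization 2 passed, without Phgdh (adjusted p = 0.264 over the list alone). For ER stress and the unfolded protein response (shift 0.10, camera adjusted p = 0.168, 17 of 23 tested members above the median gene), values were Pdia6 at 0.34, Manf at 0.25 and Creld2 at 0.31, with 0.17 to 0.42 for Creld2 when 1 array was left out. For the heat shock response (shift 0.066, camera adjusted p = 0.298, 10 of 16 tested members above the median gene), values were Fkbp4 at 0.25, Ahsa1 at 0.22 and Hspd1 at 0.13, with 0.12 to 0.27 for Ahsa1 and 0.065 to 0.21 for Hspd1 when 1 array was left out. The shifts of these lists with 1 array left out ran from 0.071 to 0.18 for ER stress and -0.012 to 0.14 for heat shock. The heat shock list was higher by 0.40 on replicates 1 and 2 than on replicates 3 and 4. Leaving out 1 array makes these sets unequal between the groups, which by itself moves the shift of the heat shock list.

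Memory precursor and naive T cell genes fell as a list, by 0.14 log2 against other genes (camera adjusted p = 0.0225, and adjusted p = 0.865 with an estimated correlation), with 18 of 25 tested members below the median gene. Bach2, a transcriptional repressor that restrains effector differentiation, stood at -0.72, with signals of 211 ± 29.9 against 309 ± 63.8. Ltb, which encodes lymphotoxin beta, stood at 0.21 and the regulator gene Id3 at 0.18, opposite to the list. Il7r, the interleukin-7 receptor alpha chain, was chosen after its values were seen and stood at -0.79, with signals of 1754 ± 493 against 2608 ± 612. Its groups overlapped (exact permutation p = 0.0857), and its second probe set stood at -0.69 (exact permutation p = 0.343). The limma adjusted p of Il7r over all alternatives ran from 0.160 to 0.655. No member passed over all genes or adjusted over the list alone, and 2 passed adjusted over the list alone in the lower direction after quantile normalization. The call was lost without control replicate 3 (shift -0.13, adjusted p = 0.0520) or Atg7-deleted replicate 1 (-0.11, adjusted p = 0.0941), and with no filter on dim genes (-0.086, adjusted p = 0.160). The shift was -0.14 within replicates 1 and 2 and -0.14 within 3 and 4. Cytotoxic effector genes did not pass (shift -0.054, camera adjusted p = 0.155, 10 of 32 tested members above the median gene), with Il12rb2 at 0.37, Serpinb9 at 0.34 and Tnf at 0.65, of which the range with 1 array left out was 0.35 to 1.03 for Tnf and 0.21 to 0.48 for Il12rb2. Inhibitory receptor and exhaustion genes did not pass either, with a mean shift of 0.035, a median of -0.038 and a downward test (camera adjusted p = 0.709), and their values were Ikzf2 at 0.51, Cd244a at 0.36 and Tox2 at 0.49, with 0.30 to 0.75 for Tox2 when 1 array was left out. As lists, single arrays left out gave -0.11 to 0.0091 for cytotoxic effector genes and -0.051 to 0.16 for inhibitory receptors.

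Immediate early genes, which are induced within minutes of stimulation, stood lower in the Atg7-deleted cells as a list, with 23 of 24 members below the median gene. The list fell by 0.27 (camera adjusted p = 1.16e-04, and adjusted p = 0.865 with an estimated correlation), while the exact permutation p of the list's mean per array was 0.514. That permutation does not keep replicates 1 and 2 apart from 3 and 4, a division that moved this list by 1.10. Within each of these sets both Atg7-deleted arrays lay below both control arrays, and with the division as a term, chosen after seeing the data, the camera adjusted p was 2.15e-05, and adjusted p = 0.858 with an estimated correlation. The members with the smallest p were Btg2 at 0.036, Ier2 at -0.0024 and Fosl2 at -0.020, and 0 passed over all genes or adjusted over the list alone. Arrays of the same genotype differed more than the genotypes did: Fos read 4621, 4742, 798 and 227 on control arrays 1 to 4 and 3103, 4640.0, 146 and 64.3 on Atg7-deleted arrays 1 to 4, a gene chosen after its values were seen. The relative log2 difference of Fos was -1.35 (exact permutation p = 0.543). Without control arrays 1 and 2 the shift of the list turned to 0.27 (adjusted p = 0.634), in a comparison where only the Atg7-deleted group held replicates 1 and 2. Leaving out 1 array makes the 2 replicate sets unequal between the groups, which by itself moves the shift of this list. The shift was -0.084, -0.10, -0.45 and -0.46 without control replicates 1, 2, 3 and 4 in turn, and -0.52, -0.093 and -0.086 without Atg7-deleted replicates 2, 3 and 4 in turn. With all arrays it was -0.27, and it was -0.26 within replicates 1 and 2 and -0.29 within replicates 3 and 4.

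**Figure D2:**
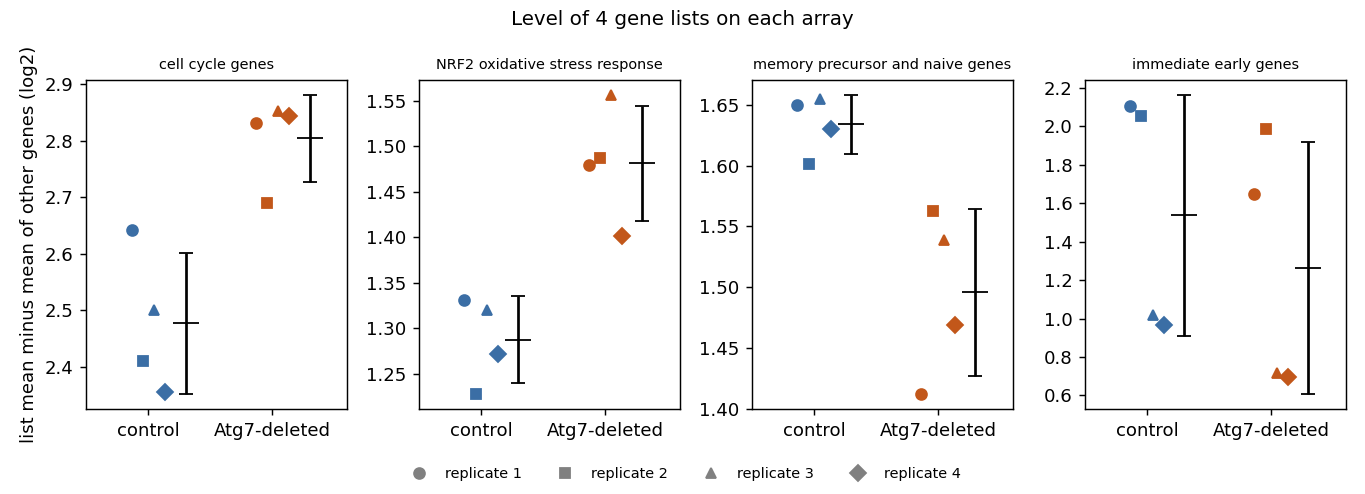
Mean log2 signal of 4 gene lists minus the mean of all other tested genes on each array, by group; symbols mark the replicate number, and the bar beside each group is the mean with its SD (n = 4). The cell cycle list lies higher on all 4 Atg7-deleted arrays, and the immediate early list separates replicates 1 and 2 from 3 and 4 in both groups.

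Lists of mitochondrial and proteasome genes shifted upward by small amounts. Their camera p-values take in the rise of the median gene and do not test these shifts themselves. The exact permutation p of the list mean per array was 0.429 for proteasome and 0.600 for oxidative phosphorylation genes. For TCA cycle and fatty acid oxidation genes it was 0.0286 and 0.0857, and none passed when adjusted over the lists. Proteasome genes rose by 0.063 (camera adjusted p = 6.86e-04, and adjusted p = 0.865 with an estimated correlation), with Psmd7 at 0.32, Psmd11 at 0.12 and Psmd13 at 0.14. Oxidative phosphorylation genes rose by 0.045 (camera adjusted p = 0.00123, and adjusted p = 0.865 with an estimated correlation), with Ndufc1 at 0.27, Uqcrfs1 at 0.17 and Uqcrq at 0.15. TCA cycle genes rose by 0.10 (camera adjusted p = 0.0197, and adjusted p = 0.865 with an estimated correlation), with Fh1 at 0.23, Sdhc at 0.14 and Sdhb at 0.13. Fatty acid oxidation genes rose by 0.092 (camera adjusted p = 0.0313, and adjusted p = 0.865 with an estimated correlation), with Decr1 at 0.32, Eci1 at 0.25 and Etfdh at 0.20. Leaving out 1 array gave 0.20 to 0.37 for Psmd7, 0.055 to 0.19 for Psmd11, 0.043 to 0.24 for Psmd13 and 0.20 to 0.44 for Decr1. It gave 0.055 to 0.19 for Sdhb and 0.085 to 0.20 for Uqcrq. Members above the median gene numbered 25 of 35, 31 of 52, 17 of 23 and 17 of 20, and in each of these 4 lists 0 members passed over all genes or adjusted over the list alone. After centring each array the calls were lost for proteasome (adjusted p = 0.0790), oxidative phosphorylation (0.239), TCA cycle (0.0790) and fatty acid oxidation (0.123), and after quantile normalization for TCA cycle (adjusted p = 0.167) and fatty acid oxidation (0.464). Without control replicate 4 they were lost for proteasome (shift 0.013), oxidative phosphorylation (9.5e-04) and fatty acid oxidation (0.070). The oxidative phosphorylation shift was 0.088, 0.075 and 0.014 without control replicates 1, 2 and 3 in turn, 0.021 and 0.029 without Atg7-deleted replicates 1 and 4, and -0.0096 with the dimmest 50% of genes left out. The proteasome shift was 0.12 and 0.031 without control replicates 1 and 3, and 0.0091 with the dimmest 50% left out, a setting that ended the TCA cycle call (shift 0.046, adjusted p = 0.111). Without Atg7-deleted replicate 4 the fatty acid oxidation shift was 0.058. Fatty acid oxidation also lost its call without control replicate 3 (adjusted p = 0.0520), Atg7-deleted replicate 1 (0.0515) or Atg7-deleted replicate 4 (0.165). Within replicates 1 and 2 the shifts were -0.074 for proteasome, -0.057 for oxidative phosphorylation, 0.094 for TCA cycle and 0.022 for fatty acid oxidation, and within replicates 3 and 4 they were 0.20, 0.15, 0.11 and 0.16.

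Autophagy genes other than Atg7 did not pass as lists. The autophagy machinery (shift -0.038, camera adjusted p = 0.755, 11 of 34 tested members above the median gene) had Atg101 at 0.20, Gabarapl1 at 0.22 and Atg4b at 0.13, and after quantile normalization its shift of -0.093 passed (adjusted p = 0.0273, and adjusted p = 0.686 with an estimated correlation). After quantile normalization Atg101, Gabarapl1 and Atg4b stood at 0.10, 0.14 and 0.040. With 1 array left out Gabarapl1 ran from 0.10 to 0.30 and Atg4b from 0.024 to 0.24. Autophagy cargo receptors (shift 0.021, camera adjusted p = 0.423, 6 of 13 tested members above the median gene) had Bnip3 at 0.33, Fkbp8 at 0.28 and Bcl2l13 at 0.17, and Bnip3, a mitophagy receptor, passed adjusted over the list alone (limma adjusted p = 0.0278, and 0.386 after quantile normalization, where the call was lost). The lysosome list had a mean and median below 0 and an upward test (shift -0.011, median -0.0096, camera adjusted p = 0.521), with Tfeb at 0.41, Gla at 0.33 and Atp6v1a at 0.12, the first being a regulator of lysosomal genes. Endocytosis and membrane traffic (shift 0.039, camera adjusted p = 0.155, 18 of 26 tested members above the median gene) had Unc13d at 0.13, Vps4a at 0.099 and Rab27a at 0.29. Leaving out 1 array gave list shifts of -0.079 to -0.013 for the machinery, 0.0067 to 0.051 for cargo receptors, -0.027 to 0.0090 for lysosome and 0.011 to 0.055 for endocytosis.

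The other metabolic lists, and the survival and signalling lists, did not pass. Glycolysis (shift 0.079, camera adjusted p = 0.0907, 10 of 21 tested members above the median gene) had 3 members that passed adjusted over the list alone, Tpi1 at 0.52, Slc16a3 at 0.49 and Hk1 at 0.23, and 0 after quantile normalization. Sterol and fatty acid synthesis (shift 0.17, camera adjusted p = 0.125, 19 of 24 tested members above the median gene) had Mvd at 0.095, Fdft1 at 0.27 and Fdps at 0.48. The list of mTORC1, amino acid and iron uptake (shift 0.066, camera adjusted p = 0.379, 13 of 24 tested members above the median gene) had Tfrc at 0.83, Eif4ebp1 at 0.54 and Depdc5 at 0.17, of which Tfrc passed adjusted over the list alone (limma adjusted p = 0.00268). Mitochondrial dynamics and biogenesis (shift 0.042, camera adjusted p = 0.155, 15 of 23 tested members above the median gene) had Tomm40 at 0.26, Mfn2 at 0.32 and Hspd1 at 0.13. Pro-apoptotic genes (shift 0.076, camera adjusted p = 0.379, 14 of 23 tested members above the median gene) had Ripk3 at 0.28, Casp1 at 0.51 and Bak1 at 0.19, and the necroptosis kinase gene Ripk3 passed adjusted over the list alone (limma adjusted p = 0.0345, and 0.618 after quantile normalization, where the call was lost). Anti-apoptotic genes (shift 0.031, camera adjusted p = 0.488, 9 of 16 tested members above the median gene) had Traf2 at 0.26, Akt1 at 0.17 and Dad1 at 0.067. The p53 target list had a mean shift of 0.020, a median of -0.0047 and a downward test (camera adjusted p = 0.873), with Cdkn1a at 1.05, Pidd1 at 0.23 and Gadd45b at 0.18, and the cell cycle inhibitor gene Cdkn1a passed adjusted over the list alone (limma adjusted p = 0.0456, and 0.0732 after quantile normalization, where the call was lost). Interferon response genes (shift 0.0084, camera adjusted p = 0.863, 16 of 33 tested members above the median gene) had Zbp1 at 0.36, Ifih1 at 0.20 and Gbp3 at 0.30. The interferon shift was -0.23 within replicates 1 and 2 (adjusted p = 0.00281, and adjusted p = 0.995 with an estimated correlation) and 0.24 within 3 and 4 (adjusted p = 0.00294, and adjusted p = 0.939 with an estimated correlation), and the difference between these sets was not tested. It was 0.12 without control replicate 1 (adjusted p = 0.0382, and adjusted p = 0.861 with an estimated correlation) and 0.16 without control arrays 1 and 2 (adjusted p = 0.0303, and adjusted p = 0.887 with an estimated correlation). With 1 array left out the differences ran from 0.22 to 0.51 for Zbp1, 0.28 to 0.64 for Fdps and 0.042 to 0.14 for Mvd. They ran from 0.034 to 0.27 for Gadd45b, 0.15 to 0.31 for Pidd1 and 0.097 to 0.29 for Bak1. Over the same fits the list shifts ran from 0.053 to 0.12 for glycolysis, 0.089 to 0.21 for sterol synthesis, 0.037 to 0.093 for mTORC1 and uptake and 0.0085 to 0.078 for mitochondrial dynamics. They ran from 0.048 to 0.10 for pro-apoptotic genes, 0.016 to 0.052 for anti-apoptotic genes, -0.014 to 0.063 for p53 targets and -0.045 to 0.12 for interferon response. Medians lay below 0 beside means above 0 for glycolysis (-0.0035), cargo receptors (-0.043) and interferon response (-9.8e-04). After quantile normalization the shift changed sign for endocytosis (-0.016), cargo receptors (-0.010), anti-apoptotic genes (-0.011), inhibitory receptors (-0.033), interferon response (-0.032), p53 targets (-0.0053) and erythroid markers (0.023). Of 698 list genes tested with limma, 0 passed over all genes and 182 had an unadjusted p under 0.05, 180 higher and 2 lower, against 65 after quantile normalization.

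Markers of other spleen cells were measured beside these groups. Macrophage and monocyte markers fell by 0.19 as a list (camera adjusted p = 1.78e-04, and adjusted p = 0.865 with an estimated correlation), with Lyz2 at -0.62 and Ms4a7 at -0.58, while Fcer1g, the Fc receptor gamma chain, stood at 1.27 with signals of 533 ± 439.6 against 155 ± 74.3. Lyz2 read 18.5 ± 8.61 against 29.5 ± 9.91 and Ms4a7 13.4 ± 6.74 against 21.4 ± 6.00, near the offset of 16. So near the offset a rise in brightness shared by all genes shows less, which lowers dim genes against the median gene. After quantile normalization, which removes the brightness difference shared by all genes, the macrophage list still fell, by 0.13. It passed there (camera adjusted p = 0.0333, and adjusted p = 0.416 with an estimated correlation). Its call was kept in 22 of 25 alternatives. Against no change, fry gave the macrophage list an adjusted p of 0.967. With the dimmest 50% of genes left out the macrophage shift was 0.076 (adjusted p = 0.124), without Atg7-deleted replicate 1 it was -0.11, and within replicates 1 and 2 and within 3 and 4 it was -0.22 and -0.15. Gamma-delta T cell markers, with 4 genes tested, fell by 0.36 (camera adjusted p = 0.0313, and adjusted p = 0.865 with an estimated correlation), with Trgv4 at -0.94, Cd163l1 at -0.014 and Il17a at -0.26. Trgv4 stood at -0.38 without control replicate 2, and between that and -1.17 with 1 array left out. The call was lost without control replicate 2 (shift -0.19) or 4 (-0.38), without Atg7-deleted replicate 1 (-0.34) or 4 (-0.32), and after quantile normalization (-0.30). It was also lost with centred arrays (adjusted p = 0.104), with no filter on dim genes (0.0523) and without _x_at and _s_at probe sets (0.0858). Its shifts were -0.46 within replicates 1 and 2 and -0.26 within 3 and 4. B cell markers had a mean shift of 0.13, a median of 0.019 and a downward test (camera adjusted p = 0.755), with Ighm at 0.22, Cd79b at 0.78 and Jchain at 1.44, the Jchain signals being 362 ± 389 against 64.2 ± 37.9. Dendritic cell markers (shift 0.10, camera adjusted p = 0.544, 5 of 9 tested members above the median gene) had Tcf4 at 0.49, Ccr9 at 0.57 and Bst2 at 0.23, and Tcf4 passed adjusted over the list alone (limma adjusted p = 0.00868, and 0.116 after quantile normalization, where the call was lost). NK cell markers (shift -0.19, camera adjusted p = 0.0846, 4 of 9 tested members above the median gene) had Klrb1b at 1.13, Cd244a at 0.36 and Kit at 0.080, signals for Klrb1b being 106 ± 101.1 against 23.1 ± 10.8. The NK list passed with a term for replicates 1 and 2 against 3 and 4 (camera adjusted p = 0.0441, and adjusted p = 0.858 with an estimated correlation), and not after quantile normalization (adjusted p = 0.639). Its shift was 0.082 within replicates 1 and 2 and -0.47 within 3 and 4. Over all alternatives the adjusted p of the NK list (camera or fry) ran from 6.87e-04 to 0.919. Neutrophil markers (shift 0.22, camera adjusted p = 0.369, 3 of 3 tested members above the median gene) had S100a9 at 0.51, S100a8 at 0.16 and Mmp9 at 0.0011. The CD4 and regulatory T cell markers (shift -0.053, camera adjusted p = 0.521, 3 of 7 tested members above the median gene) had Gata3 at 0.14, Zbtb7b at 0.22 and Ikzf4 at 0.090. Erythroid and platelet markers (shift -0.073, camera adjusted p = 0.318, 2 of 8 tested members above the median gene) had Tfrc at 0.83, Epb42 at 0.031 and Pf4 at -0.47, and Tfrc passed adjusted over that list alone as well. With 1 array left out the differences of single markers ran from 0.82 to 2.07 for Jchain, 0.51 to 1.04 for Cd79b, 0.68 to 1.46 for Klrb1b, 0.85 to 1.51 for Fcer1g, 0.30 to 0.77 for Ccr9, 0.30 to 0.65 for S100a9 and -0.57 to -0.23 for Pf4. They ran from 0.070 to 0.45 for Bst2, 0.071 to 0.40 for Zbtb7b and 0.078 to 0.21 for Gata3. Jchain, Klrb1b and Fcer1g all read highest on Atg7-deleted array 3, at log2 levels of 9.84, 8.07 and 10.23. The next highest levels in that group were 8.64, 6.76 and 8.57, so the group means of these markers lean on 1 array. The marker lists themselves ran from 0.068 to 0.20 for B cells, 0.065 to 0.13 for dendritic cells, -0.31 to -0.11 for NK cells, 0.13 to 0.31 for neutrophils, -0.093 to -0.026 for CD4 and regulatory T cells and -0.13 to 0.0061 for erythroid cells.

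Across the 33 lists, 10 passed with the preset correlation, 6 upward and 4 downward, 0 passed with an estimated correlation, and 8 passed after quantile normalization. The exact permutation p of the list mean per array was 0.0286 for cell cycle, NRF2, TCA cycle and memory precursor genes, the smallest that 4 against 4 arrays can give, which does not pass when adjusted over the lists (adjusted p = 0.236). It was 0.0857 for fatty acid oxidation and for macrophage markers, 0.0571 for gamma-delta markers, 0.429 for proteasome and 0.600 for oxidative phosphorylation genes.

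**Figure D3:**
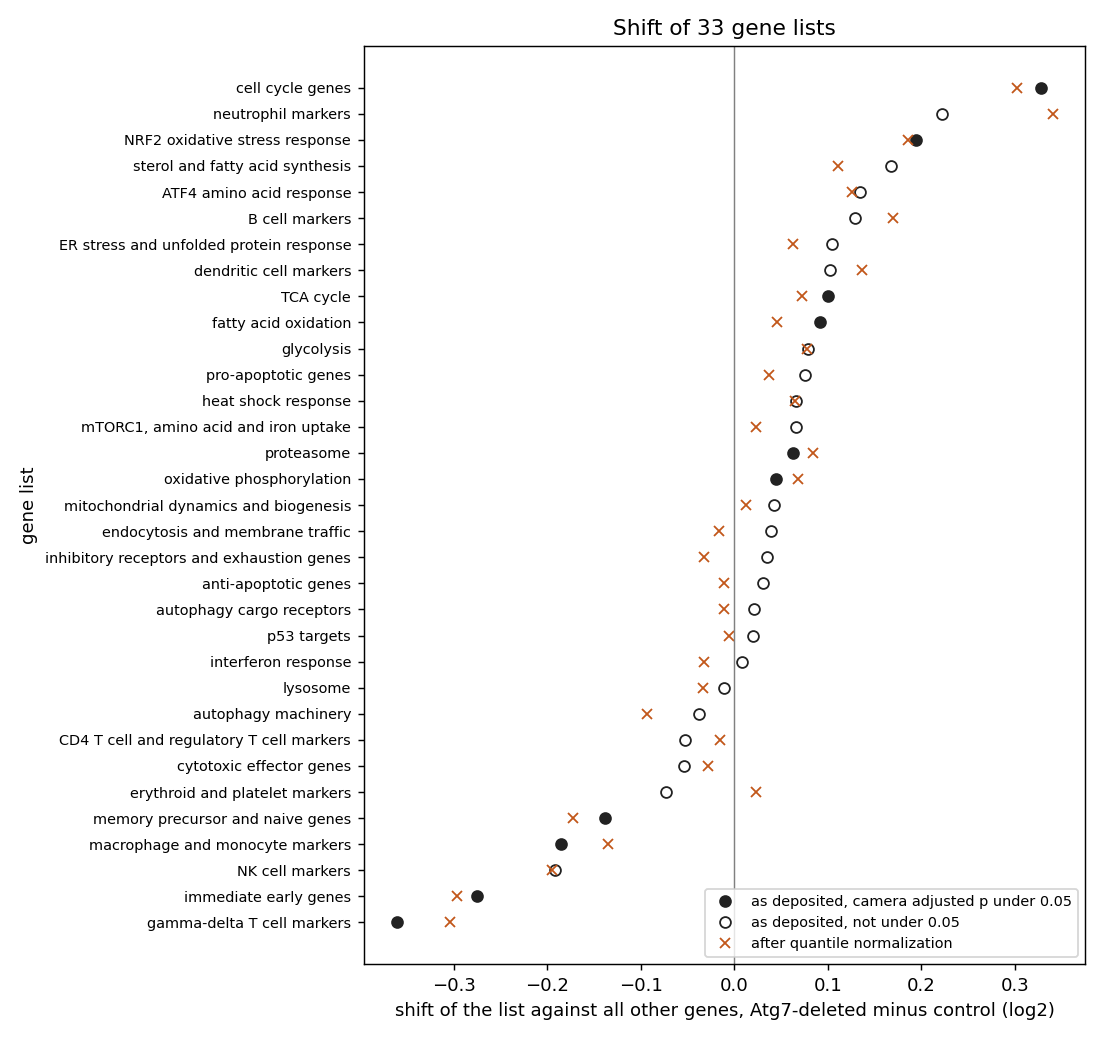
Shift of each of the 33 gene lists against all other tested genes, Atg7-deleted minus control on the log2 scale; circles are the deposited values, filled where the camera adjusted p was under 0.05, and crosses are after quantile normalization. Cell cycle genes lie at 0.33 and 0.30, and gamma-delta T cell markers at -0.36 and -0.30.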

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

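The checks for single arrays and the counts of other splits for genes and for lists followed rules set beforehand, and quantile normalization was among the settings chosen beforehand. Its use as a test of brightness for cell cycle and immediate early genes, and the other tests on these genes, were chosen only after the result was seen, and what each test, split counts included, should show was written down after its result. One array stood far from the other 3 of its group in 17 of 314 checks of named genes and lists, where chance flags about 1 in 20, or 15.7. As log2 levels, Eno2 read 6.00 on Atg7-deleted 2 and 5.62 to 5.65 on the others of its group. Cdkn1a read 10.53 on Atg7-deleted 3 and 9.38 to 9.50 on the others of its group. Gadd45b read 9.76 on control 4 and 10.16 to 10.21 on the others of its group. Ndufc1 read 12.63 on Atg7-deleted 3 and 12.26 to 12.29 on the others of its group. Phgdh read 11.56 on Atg7-deleted 3 and 11.28 to 11.32 on the others of its group. Psmd11 read 11.24 on control 1 and 11.14 to 11.16 on the others of its group. Atp6v1a read 11.16 on Atg7-deleted 3 and 10.98 to 11.01 on the others of its group. Ighm read 9.14 on control 1 and 9.31 to 9.34 on the others of its group. Fcer1g read 8.14 on control 3 and 7.01 to 7.13 on the others of its group. S100a9 read 4.13 on control 1 and 5.09 to 5.19 on the others of its group. Trgv4 read 7.17 on control 2 and 5.11 to 5.32 on the others of its group. Cd163l1 read 7.25 on Atg7-deleted 2 and 6.27 to 6.42 on the others of its group. As list means relative to all other genes, the list of autophagy cargo receptors read 1.79 on Atg7-deleted 3 and 1.89 to 1.91 on the others of its group. The list of cell cycle genes read 2.69 on Atg7-deleted 2 and 2.83 to 2.85 on the others of its group. The list of sterol and fatty acid synthesis read 1.98 on Atg7-deleted 3 and 1.63 to 1.68 on the others of its group. The list of ER stress and unfolded protein response read 2.09 on Atg7-deleted 4 and 2.37 to 2.41 on the others of its group. The list of CD4 T cell and regulatory T cell markers read -1.99 on Atg7-deleted 2 and -2.14 to -2.12 on the others of its group. Outside the comparison, of 6623 tested probe sets with several gene names or none, limma called 0, and 547 had an unadjusted p under 0.05.

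The real grouping gave 1 gene past the threshold, and 4 of the 35 splits of the 8 arrays gave at least as many, the real one included, with 24 as the highest of the others, so chance cannot be excluded for the count of genes. The split with 24 genes set replicates 1 and 2 of both genotypes against 3 and 4, which points to a structure of the samples. With that division as a term of the fit, 5 genes passed between genotypes, Abcb6, Dab2ip, Irak3, Nqo1 and Prickle1, and 0 did with that term and quantile normalization (limma, 1302 at an unadjusted p under 0.05). For lists, the real grouping gave 10, and 3 of 35 splits gave as many, the highest other being 13, so chance cannot be excluded for the number of lists. Those splits mix replicates 1 and 2 with 3 and 4, and over the 18 splits with equal numbers of both sets in each group, which are too few for a share under 0.05, the highest other was 1 gene and 12 lists.

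The upward shift of cell cycle genes was 0.33, and 1 of 35 splits reached it, the highest other being 0.30. Among these splits this argues against chance for the list taken alone, but they mix replicates 1 and 2 with 3 and 4, and the list was picked from 33. Over the 18 splits with equal numbers of both sets in each group, which are too few for a share under 0.05, the highest other was 0.30, and the camera p of the list with an estimated correlation was 0.0870 before adjustment. The shift is taken against all other genes, so a rise in brightness shared equally by all genes was already removed. Quantile normalization, which also evens out differences that vary with signal, left a shift of 0.30 with no overlap of the list means between groups. This argues against differences in brightness that vary with signal. A biological difference in cycling between the genotypes stays open as a hypothesis found and tested on the same arrays, and a difference in handling or sorting between the genotypes, which was not tested, stays open too.

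Immediate early genes were higher on replicates 1 and 2 than on 3 and 4 in both genotypes, by 1.10 as a list (exact permutation p = 0.0286, the smallest possible), by 1.09 among control and 1.11 among Atg7-deleted arrays. The list mean is taken against all other genes, so a rise in brightness shared equally by all genes was already removed. Quantile normalization, which also evens out differences that vary with signal, left the difference at 1.10. This argues against differences in brightness that vary with signal. The separately fixed heat shock list was also higher on all arrays of replicates 1 and 2, by 0.40, which is consistent with a difference in handling stress between these sets of samples. The labels name no batch, and no biological explanation was tested. In the fit with this division as a term, 33 genes passed for it, among them Fos (difference 4.23, adjusted p = 0.0121) and Jun (2.52, adjusted p = 0.0244), and 0 passed for its interaction with genotype, where 1918 had an unadjusted p under 0.05. The division, Fos and Jun were chosen after their values were seen. The p-values of the division for the immediate early list and for these genes therefore describe the pattern and do not test it.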

How the results depend on the processing

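The replicate-set term (replicates 1 and 2 against 3 and 4), the fits within these sets and the fit without control arrays 1 and 2 were chosen after seeing the data, and the other alternatives were planned. The Atg7 difference kept its direction throughout, from -0.73 with the mean of its probe sets to -2.94 within replicates 3 and 4. It passed when arrays were centred (-2.43), and ran from -2.81 to -2.25 with 1 array left out. Against 1 gene passing, the count was 0 with no filter on dim genes, array weights, the replicate-set term and quantile normalization, control arrays 1 and 2 left out, replicates 1 and 2 alone, replicates 3 and 4 alone and every probe set tested, 2 with quantile normalization and the mean of a gene's probe sets, 3 with the dimmest 50% left out and an offset of 64 and 5 with centring on array medians and the replicate-set term, and 0 to 1 with 1 array left out. Against 10 lists passing, the count was 6 with centring, 5 within replicates 1 and 2, 5 with fry, 0 with an estimated correlation, 15 with the mean of a gene's probe sets, 13 with no filter on dim genes, 13 with an offset of 64, 8 to 11 with the other alternatives, and 6 to 14 with 1 array left out. Fewer arrays lower the power of the fits that leave arrays out, and for the other changes the cause was not tested. Arrays were not treated as pairs, since the labels state nothing shared by a number and not every same-numbered correlation exceeded 0.1. The deviations correlated at 0.123, 0.0179, 0.281 and 0.128 for replicates 1 to 4, and 5 of 8 arrays correlated best with the same number among arrays of the other genotype. With the replicate number as a block (replicate block), 1 gene and 10 lists passed. For lists, 659 values under alternatives kept direction and side of the threshold, 53 lost the call, 37 gained one and 71 reversed, and for named genes the numbers were 2667, 12, 13 and 105. Signals near the offset of 16 limit what can be read from dim genes. Most reversed values belonged to genes and lists near 0, and the list direction is that of the test, which the shift need not follow. With the mean of a gene's probe sets, Atg4b -0.018, Btg2 -0.018, Depdc5 -0.030, Epb42 -0.23, Fkbp4 -0.17, Fosl2 0.10, Gla -0.091, Ier2 0.0089, Kit -0.0020, Uqcrq -0.16, p53 targets 0.034. With replicates 1 and 2 alone, Atg4b -0.13, Atp6v1a -0.029, Bak1 -0.010, Bst2 -0.089, Cd163l1 0.25, Dad1 -0.054, Fkbp4 -7.6e-05, Fosl2 0.13, Hspd1 -0.0096, Ighm -0.034, Ikzf4 -0.059, Kit -0.25. Also with replicates 1 and 2 alone, Ltb -0.073, Mmp9 -0.055, Pidd1 -0.12, Psmd11 -0.023, Psmd13 -0.14, Sdhb -0.022, Unc13d -0.024, Vps4a -0.072, Zbp1 -0.014, ATF4 amino acid response 0.061, autophagy machinery 0.0039, dendritic cell markers 0.057. Also with replicates 1 and 2 alone, glycolysis -0.027, heat shock response 0.071, interferon response -0.23, oxidative phosphorylation -0.057, p53 targets 0.016, proteasome -0.074. With quantile normalization, Btg2 -0.030, anti-apoptotic genes -0.011, cargo receptors -0.010, B cell markers 0.17, endocytosis -0.016, erythroid markers 0.023, interferon response -0.032, lysosome -0.034. With the dimmest 50% left out, Btg2 -0.0062, anti-apoptotic genes -0.022, B cell markers 0.49, interferon response -0.024, lysosome -0.059. With the replicate-set term and quantile normalization, Btg2 -0.030, anti-apoptotic genes -0.011, cargo receptors -0.010, B cell markers 0.17, endocytosis -0.016, erythroid markers 0.023, interferon response -0.032, lysosome -0.034. With control arrays 1 and 2 left out, Btg2 -0.13, Cyp4f16 1.92, Fos 0.51, H2-Oa 1.31, Ier2 0.44, Jun 1.20, Zbtb7b -0.0040, B cell markers 0.27, immediate early genes 0.27, inhibitory receptors 0.13, p53 targets 0.088. With replicates 3 and 4 alone, Btg2 -0.21, Cyp4f16 1.84, Epb42 -0.24, H2-Oa 1.27, Ier2 0.052, B cell markers 0.23, inhibitory receptors 0.073. With no filter on dim genes, Cd163l1 0.046, Cyp4f16 0.057, Fosl2 0.039, Ier2 0.057, autophagy machinery 0.014, inhibitory receptors 0.087, neutrophil markers -0.021, p53 targets 0.072. With array weights, Cd163l1 0.055, Cyp4f16 0.19, H2-Oa 0.067, Ier2 0.15, Jun 0.40, Mmp9 -0.025, interferon response -0.022, p53 targets 0.048. With _x_at and _s_at probe sets left out, Cdc23 -0.59, Tgm2 0.063, Uqcrq -0.19. With an offset of 64, Epb42 -0.078, Fosl2 0.020, Ier2 0.032, Ikzf4 -0.036, Kit -0.069, Mmp9 -0.085, S100a8 -0.016. With fry, autophagy machinery -0.038, B cell markers 0.13, CD4 and regulatory T cell markers -0.053, cytotoxic effector genes -0.054, erythroid markers -0.073, immediate early genes -0.27, inhibitory receptors 0.035, memory precursor genes -0.14, NK cell markers -0.19, p53 targets 0.020. With centring on array medians, B cell markers 0.13, inhibitory receptors 0.035, lysosome -0.011. With a variance trend, p53 targets 0.020. With the replicate number as a block, p53 targets 0.020. With 1 array left out the ranges were Btg2 -0.037 to 0.13, Cd163l1 -0.23 to 0.095, Cyp4f16 -0.65 to 0.68, Dad1 -0.025 to 0.14, Epb42 -0.067 to 0.12, Fosl2 -0.14 to 0.11, H2-Oa -0.60 to 0.41, Ier2 -0.18 to 0.17, Ikzf4 -0.048 to 0.21. Further such ranges were Jun -0.79 to 0.43, Kit -0.085 to 0.20, Mmp9 -0.072 to 0.062, autophagy machinery -0.079 to -0.013, B cell markers 0.068 to 0.20, inhibitory receptors -0.051 to 0.16, interferon response -0.045 to 0.12, p53 targets -0.014 to 0.063. Against no change, rather than against other genes, fry called 5 lists and pointed upward for 31 of 33, a test that takes in the 0.22 of the median gene. Its 10 reversals, counted among the 71, are printed with the list's shift and do not show a list turning against other genes.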

Other observations

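Prickle1, a planar cell polarity gene chosen after its values were seen, stood at 1.73 relative log2 (limma adjusted p = 0.120), with signals of 599 ± 269.8 in Atg7-deleted cells against 136 ± 42.3 in control cells. Its other probe sets, which were dim, stood at 0.17 and -0.16, and the mean of its probe sets at 0.59. Prickle1 passed with a term for replicates 1 and 2 against 3 and 4 (adjusted p = 0.0421), and its adjusted p over all alternatives ran from 0.0421 to 0.467. The array's own control probe sets for Tfrc, which took no part in the gene comparison, read 103 ± 28.3 against 51.0 ± 8.29 for the middle of the transcript, 38.2 ± 27.7 against 6.27 ± 2.06 for the 5' part and 453 ± 182 against 241 ± 84.4 for the 3' part, with adjusted p of 0.0595, 0.102 and 0.473 over the 64 control probe sets.

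H2-Oa, which encodes a class II accessory chain, and Cyp4f16, chosen after their values were seen, each fell into separate levels that did not follow genotype. H2-Oa read 1587, 1753, 309 and 267 on control arrays 1 to 4 and 261, 2261, 2006 and 276 on Atg7-deleted arrays 1 to 4. Cyp4f16 read 477, 547, 29.8 and 29.2 on the same control arrays and 41.8, 590.1, 544 and 37.0 on the Atg7-deleted arrays. Both genes were thus high on control arrays 1 and 2 and Atg7-deleted arrays 2 and 3, and low on all others. No explanation of these levels was tested.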
